A study of Lens culinaris with 50 samples.

How the data were processed

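RNA was measured in embryo, seed coat and whole seed of lentil at 8 embryo stages and in the unfertilized ovule, which the labels class with the whole seed. Per the labels' protocols, plants were kept at 22 °C for 16 h of light at 100 to 120 µmol per m2 and s and at 20 °C for 8 h of dark, flowers were hand-pollinated after emasculation, and tissues were dissected in 4.8% sucrose with 0.1% RNAlater. Libraries were made with a kit for low RNA input, per the labels' protocols; such kits amplify the RNA, and how strongly is not given in the sources used here. The submitters' processing notes name CASAVA, Trimmomatic, featureCounts and DESeq2 without versions or roles. The aligner and the genome build are not given in the sources used here.

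The deposited table gives 1 signal value per gene and library, which the authors made from read counts by division with 1 factor per library. Each value above 0 was a whole multiple of the smallest such value of its library, so whole reads could be recovered for 100% of the values within a tolerance of 0.001 reads. The factors equal DESeq2's median-of-ratios factors computed from these reads, with the largest deviation at 6.77e-13%. Values in this scale are called normalized reads. The libraries held 13019472 to 35634980 recovered reads. Intervals and floors cover counting error only, since reads after amplification are not independent molecules. For a group of libraries at 0, a floor of 3 counts per library was used, and for groups with 1 to 3 counts a 95% counting interval of the ratio. The ratio takes the reads summed over the libraries of a group, divided by their summed factors, so it can differ from the ratio of the printed means.

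Replicates are separate samples in the labels. Nothing says whether they came from separate plants, so p-values of the gene tests measure the spread between these samples, which may be technical. No pair of replicates differed by as little as sampling noise: the mean chi-square per gene with 1 degree of freedom was at least 14.7 in each of the 25 pairs.

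Groups, comparisons, tests, the rule for named genes and the alternatives other than those named at the end of their list were fixed before the data were examined. The main test was limma (version 3.58.1, R 4.3.3) with trend and robust options on log2(normalized reads + 1), with 1 coefficient for each of the 25 groups and 25 residual degrees of freedom. A fold change on this scale understates the change of genes with few reads. Genes with at least 10 normalized reads in at least 2 libraries were tested, 29440 of 58243. A gene counted as changed with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes and a fold of at least 2. The comparisons were ovule to zygote, embryo versus seed coat at each of 8 stages and over their mean, 7 consecutive steps in embryo and in seed coat, mature versus zygote in each tissue, its interaction between embryo and seed coat, and a moderated F-test over stages. Whole seed was also compared with embryo and with seed coat at each stage in the same model.

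The embryo weight of the whole seed was found by least squares over genes that differed between embryo and seed coat with at least 100 normalized reads in 1 of them. Each gene was weighted by the inverse of the sum of its means, and the embryo weight was held between 0% and 100%. Library summaries of embryo and seed coat were compared over the 8 stages with an exact two-sided sign-flip permutation test, adjusted over 3 measures. This test takes the 8 stage differences of group means as independent, which consecutive stages of the same tissues need not be. Its p measures how steady the difference is over stages and not the spread between replicates. The numbers expected for independent lists are products of the list sizes divided by the genes tested.

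The named genes are the 2 with the largest fold in each direction for 4 comparisons: ovule to zygote, embryo versus seed coat over the 8 stages, and mature versus zygote in embryo and in seed coat. Each had at least 100 normalized reads in the higher group and both replicates of the higher group above both of the lower, in at least 7 of 8 stages for the comparison over stages. The table pairs 0 identifiers with names, so none of the 15 gene lists fixed in advance (such as seed storage proteins, cell division or flavonoid synthesis) could be tested, and no functions are given.

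The alternatives were pseudocounts of 0.5 and 8, no filter, a filter of at least 50, TMM and quantile scaling, library weights per group, a block on the replicate number, the spread of the compared tissues alone, no fold required, leaving out each replicate or stage, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads with the deposited factors. Chosen after seeing the data were the alternatives without the 5 libraries with few genes at 0, without genes that follow the gene set described with the seed coat steps (a correlation of at least 0.7 either way over the 50 libraries), and with at least 100 normalized reads in the higher group.

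The test was tried on simulated reads with 100 genes changed 2-fold and 100 changed 4-fold per comparison. The simulated genes were independent, with 1 dispersion per gene for all groups and no other group differences. The real groups had unlike spreads, with library weights per group from 0.319 to 3.218. The recovery and the false calls below may therefore not hold for the real data. For ovule to zygote, 89% of the 4-fold and 25% of the 2-fold changes were found, with 2 false calls among 26403 genes. For embryo versus seed coat over the 8 stages these were 97% and 38%, with 2 false calls among 26384 genes, and for mature versus zygote in embryo 88% and 32%, with 11 false calls among 26449. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the summaries and figures.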

Results

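Messenger RNA was profiled in developing seeds of lentil (Lens culinaris, cultivar CDC Gold), a legume crop grown for its protein-rich seeds. The embryo, the seed coat and the intact whole seed were sampled at 8 stages of embryo development, named zygote, quadrant, globular, heart, torpedo, early bent, late bent and mature, and the unfertilized ovule was sampled as the stage before fertilization. The seed coat sample was the tissue left after the embryo had been dissected out by hand. Each of the 25 combinations of tissue and stage had 2 libraries, 50 in all. The table held 58243 genes, of which 2323 were at 0 in all libraries, and 29440 were abundant enough to be tested. The libraries held 13019472 to 35634980 reads assigned to genes, with a median of 23945567. The Spearman correlation across genes between the 2 replicates of a group lay between 0.936 and 0.988. The table does not pair its gene identifiers with names or functions, so genes are given by identifier and gene groups by their pattern over tissues and stages.

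Embryo and seed coat followed separate paths over development. The first principal component of the 50 libraries, 28.9% of the variance, ran from young embryos to late seed coats, and the second, 22.9%, set embryos past the zygote stage apart from the seed coats. Embryo and seed coat were most alike at the zygote stage, with a Spearman correlation across genes of 0.923 between their mean profiles, and least alike at the mature stage, where it was 0.770. Within each tissue the profile at the mature stage also lay far from that at the zygote stage, with a correlation of 0.751 in embryo and 0.756 in seed coat. The unfertilized ovule was closest to the whole seed at the zygote stage (0.949) and to the seed coat at the zygote stage (0.944), and farther from the zygote stage embryo (0.886). These correlations describe group means across genes, which are not independent replicates, and no test was made on them.

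**Figure D1:**
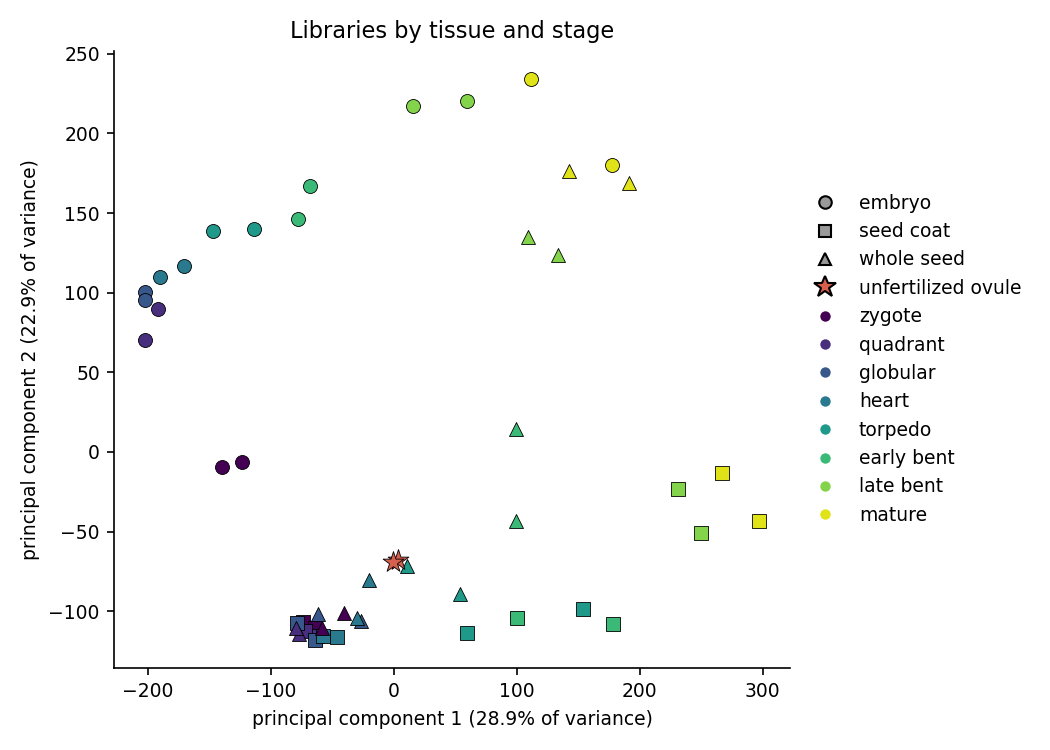
The 50 libraries on the first and second principal components of log2(value + 1), 28.9% and 22.9% of the variance, with symbols for tissue and colours for stage. Whole seed libraries lie with the seed coats at the early stages and near the embryos at the late bent and mature stages.

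The step from unfertilized ovule to the whole seed at the zygote stage was compared to find the genes that changed across fertilization. A total of 1150 genes differed, 483 higher after fertilization and 667 lower, with a median fold of 5.66 among the risers and 9.02 among those that fell. The gene Lcu.2RBY.3g072190 rose from 2.85 ± 1.62 normalized reads in the ovule to 2287 ± 239 at the zygote stage (SD, n = 2; log2 fold change 9.28, SE 1.00, adjusted p = 3.87e-07), and in the seed coat it stood at 20597 by the late bent stage. Lcu.2RBY.2g006400 rose from 0.97 ± 0.24 to 602.8 ± 441 (SD, n = 2; adjusted p = 1.13e-05), a ratio of 603 with a 95% counting interval of 206 to 2928 over 3 ovule reads. In the other direction, Lcu.2RBY.1g001060 fell from 1836 ± 121 to 3.67 ± 1.15 (SD, n = 2; log2 fold change -8.64, SE 0.79, adjusted p = 1.14e-08), and Lcu.2RBY.6g014730 fell from 668 ± 380 to 0.57 ± 0.01 (SD, n = 2; adjusted p = 4.58e-08), a ratio of 1100 with a 95% counting interval of 304 to 9092 over 2 reads.

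The genes that rose across fertilization were more often higher in seed coat, and less often higher in embryo, than independent lists would give. Of the 483 risers, 155 were higher in seed coat than in embryo at the zygote stage, where independent lists would share 40, and 31 were higher in embryo, where they would share 47.8. Of the 667 genes that fell, 181 were higher in embryo (66 for independent lists) and 19 were higher in seed coat (55.2). The embryo and seed coat libraries of this comparison were not among those of the ovule step, but the overlap is no separate evidence. At the zygote stage the whole seed was close to the seed coat, with a Spearman correlation of 0.989 and 7 genes that differed. A gene that rose in this whole seed thus tends to be high in the seed coat by composition. The embryo weight of the whole seed was 2.91% at this stage, so changes within the embryo are hardly visible in the ovule step. Between the zygote and mature embryo 258 of the 483 risers fell, against 123.2 for independent lists. Of the 667 genes that fell across fertilization, 280 rose between these embryo stages, against 186.1. The zygote stage embryo libraries held transcripts typical of the seed coat, described below. For the risers, loss of such transcripts, if carried over in dissection, cannot be told apart here from a change in the embryo. The ovule libraries had fewer genes at 0 (19.9% ± 2.46) than the whole seed libraries at the zygote stage (38.9% ± 0.17; SD, n = 2). With quantile scaling 54.7% of the called genes were higher after fertilization, against 483 of 1150 with the deposited scaling. The number of genes dropped to 466 (201 higher, 265 lower) and 409 (197 and 212) without ovule replicate 1 or 2, and to 486 (220 and 266) and 590 (286 and 304) without whole seed zygote replicate 1 or 2. It rose to 2619 (672 higher, 1947 lower) without the 5 libraries with few genes at 0 described with the seed coat steps, an alternative chosen after seeing the data, and to 4794 (1112 higher, 3682 lower) with library weights per group. Among the 543 called genes with at least 100 normalized reads in the higher group, also chosen after seeing the data, the balance turned, with 327 higher after fertilization and 216 lower. With no filter 462 were higher and 1243 lower, and by DESeq2 773 were higher and 782 lower.

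Embryo and seed coat were compared at each stage, since the series sets these tissues side by side. At the zygote stage 5351 genes differed, 2914 higher in embryo and 2437 higher in seed coat, a balance that turned with TMM scaling (2552 and 3056) and with quantile scaling (2712 and 2833). The seed coat-high genes at this stage were 1615 and 1500 without seed coat replicate 1 or 2, and 1621 without embryo replicate 2. The number of genes that differed was 10927 at the quadrant stage (4871 higher in embryo, 6056 in seed coat), 7958 at globular (3553 and 4405) and 7972 at heart (3273 and 4699). It reached 12181 at torpedo (4055 and 8126), 12204 at early bent (4051 and 8153), 12011 at late bent (5211 and 6800) and 11848 at mature (5389 and 6459). At the quadrant stage the balance turned among called genes with at least 100 normalized reads in the higher group (3749 higher in embryo, 3699 in seed coat). At the zygote stage 729 embryo-high genes and 37 seed coat-high genes differed by over 16-fold, whereas at the mature stage there were 906 and 1854. Of the 29440 genes, 24069 differed between the tissues at 1 or more stages, and 4613 of these were higher in embryo at some stage and higher in seed coat at another.

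The zygote stage embryo libraries also held transcripts typical of the seed coat. Expression in the embryo cannot be told apart from RNA carried over in dissection from part of the seed coat. Such carry-over would also make the tissues more alike at this stage and lower the number and folds of seed coat-high genes. The spread of the levels lay between the bounds set for 1 common share of the seed coat level and for separate levels. A set of 213 genes with at least 1000 normalized reads in the zygote stage seed coat and under 5% of the seed coat level in the quadrant stage embryo was chosen after seeing the data. Their median level in the zygote stage embryo was 31.7% of that in the seed coat, with quartiles of 21.1% and 43.7%. The level was under 10% for 9 of the 213 genes and lowest at 1.90%. This argues against carry-over of all seed coat RNA alike as the whole source of the median level. In the globular stage embryo, which took no part in the choice, the median was 1.72% of the globular seed coat level. In the mature embryo it was 22.4% of the mature seed coat level, which can lie far below that at the zygote stage. In seed coat Lcu.2RBY.7g001290 of this set fell from 122812 at zygote to 39.01 at mature, against 5.89 in the mature embryo. The 22.4% thus need not mean a return to the zygote stage level. At the torpedo stage 7654 genes differed without seed coat replicate 2 (2924 higher in embryo, 4730 in seed coat), 8062 with library weights per group (3276 and 4786), and the seed coat-high genes were 5354 without embryo replicate 1. At early bent the seed coat-high genes were 5010 without seed coat replicate 2, which is 1 of the 5 libraries with few genes at 0 described with the seed coat steps, and 12886 with no filter. With quantile scaling the share of called genes that were higher in embryo was 54.5% instead of 33.3% at torpedo, 54.3% instead of 33.2% at early bent, 53.9% instead of 43.4% at late bent and 54.5% instead of 45.5% at mature.

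**Figure D2:**
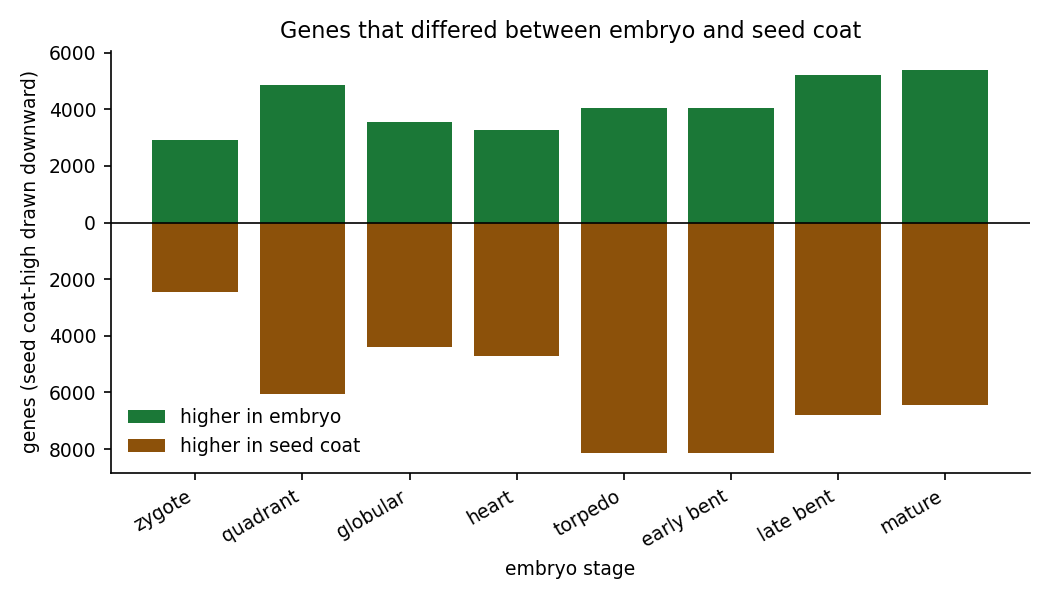
Number of genes that differed between embryo and seed coat at each of the 8 stages (limma, adjusted p under 0.05 and at least 2-fold), upward for genes higher in embryo and downward for genes higher in seed coat. The number was 5351 at the zygote stage and 10927 at quadrant, fell to 7958 at globular, and lay between 11848 and 12204 from torpedo to mature.

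Averaged over the 8 stages, 11441 genes differed between the tissues, 3725 higher in embryo and 7716 higher in seed coat. At every one of the 8 stages 308 genes were higher in embryo and 488 were higher in seed coat. The 308 genes had a median of 864 normalized reads in embryo against 101 in seed coat at the zygote stage, and 791 against 99.6 at the mature stage. The 488 genes had a median of 266 in seed coat against 61.5 in embryo at the zygote stage, and 766 against 25.9 at the mature stage. Between these stages their embryo median fell to 10.95 at globular and stood at 30.87 at late bent, while that in seed coat was 260 at globular and 781 at late bent; no test was made on these medians. With quantile scaling, which moved the median of all genes by 0.28 on the log2 scale in favour of the embryo, 51.1% of the called genes were higher in embryo, against 32.6% with the deposited scaling.

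The genes with the largest difference over the 8 stages were taken from those with both replicates of 1 tissue above both of the other in at least 7 of 8 stages. Lcu.2RBY.6g042510 stood at 1533 ± 302 in the zygote stage embryo and 2.30 ± 3.25 in the seed coat, and at 7432 ± 2375 and 20.8 ± 12.2 at the mature stage (SD, n = 2; log2 difference over the 8 stages 10.11, SE 0.27, adjusted p = 2.16e-23). Lcu.2RBY.5g050180 rose within the embryo from 20963 ± 4865 at the zygote stage to 1158137 ± 114491 at late bent (SD, n = 2), while the seed coat held 17.7 ± 9.35 and 4912 ± 1354 (log2 difference over the 8 stages 9.81, SE 0.23, adjusted p = 6.69e-25). On the seed coat side, Lcu.2RBY.4g074460 rose from 15641 ± 1194 at the zygote stage to 400246 ± 11211 at the mature stage, against 333 ± 81.9 and 192 ± 0.61 in embryo (SD, n = 2; log2 difference -8.99, SE 0.22, adjusted p = 2.72e-24). Lcu.2RBY.2g017770 stood at 4544 ± 573 in the zygote stage seed coat and 25290 ± 2799 at the mature stage, against 120 ± 29.6 and 18.4 ± 2.20 in embryo (SD, n = 2; log2 difference -8.55, SE 0.40, adjusted p = 1.71e-17).

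Some genes exchanged tissue during development. A total of 512 genes were higher in seed coat at the zygote stage and higher in embryo at the mature stage, where independent lists would share 446. Their median fell from 462 to 42.02 in seed coat and rose from 140 to 451 in embryo. The reverse exchange, from embryo to seed coat, was found for 458 genes, fewer than the 639 that independent lists would share. Their median fell from 223 to 17.99 in embryo and rose from 25.2 to 226 in seed coat. Genes that were higher in the same tissue at both ends were more frequent than for independent lists, with 849 in embryo (533) and 1003 in seed coat (535).

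The embryo changed in more genes at the steps before globular and after early bent than at those between. Between zygote and quadrant 4907 genes changed, 1074 up and 3833 down, and between quadrant and globular 4164 changed, 2385 up and 1779 down. From globular to heart 378 genes changed (149 up, 229 down), from heart to torpedo 1464 (945 up, 519 down) and from torpedo to early bent 2226 (1192 up, 1034 down). From early bent to late bent 6777 genes changed (3431 up, 3346 down) and from late bent to mature 7968 (4299 up, 3669 down). The genes that fell from zygote to quadrant had a median fold of 5.58, and 417 of them fell by over 16-fold. At the zygote stage 949 of these 3833 genes were higher in seed coat than in embryo, against 317.3 for independent lists. Another 303 were higher in embryo, against 379.4. These comparisons share the zygote stage embryo libraries. Whether seed coat-typical transcripts in these libraries came from expression in the embryo or from carry-over of part of the seed coat is open. With no fold required 2546 genes rose and 4118 fell at this step. With quantile scaling 38.9% of the genes that changed at this first step rose, against 21.9% with the deposited scaling.

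The size of the embryo steps depended on single libraries, and the balance of up and down on libraries and processing. From zygote to quadrant 682 genes rose without zygote replicate 1 and 560 without quadrant replicate 2, and from quadrant to globular 1128 fell without globular replicate 2. From globular to heart the number was 156 (102 up, 54 down) and 194 (54 up, 140 down) without globular replicate 1 or 2, and 67 up and 192 down or 178 up and 80 down without heart replicate 1 or 2; by DESeq2 it was 271 up and 258 down. From heart to torpedo it was 920 (722 up, 198 down), 914 (517 up, 397 down) and 903 (623 up, 280 down) without heart replicate 1, heart replicate 2 or torpedo replicate 2, and 707 up and 272 down without torpedo replicate 1. From torpedo to early bent it was 1420 (819 up, 601 down) without torpedo replicate 1, 1049 (569 up, 480 down) without early bent replicate 2, and 871 up and 622 down without torpedo replicate 2. From early bent to late bent it was 4491 (2601 up, 1890 down) without early bent replicate 1 and 4208 (2271 up, 1937 down) without late bent replicate 2. With TMM and quantile scaling the balance turned from torpedo to early bent (1115 up and 1147 down, 837 up and 935 down) and from early bent to late bent (3328 up and 3449 down, 2938 up and 2973 down), the latter also without the 5 libraries with few genes at 0 (3612 up, 3751 down).

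From late bent to mature the number was 4438 (2326 up, 2112 down) without late bent replicate 1, 4782 (2257 up, 2525 down) without mature replicate 2, and 6649 up and 3792 down without mature replicate 1. More genes fell than rose at this step in 10 of 18 alternatives. Besides the one without mature replicate 2 these were TMM scaling (3637 up, 4265 down), quantile scaling (3287 and 3763), edgeR (3024 and 3157), DESeq2 (3101 and 3426), library weights (1989 and 2110), a filter of at least 50 (3094 and 3572), a pseudocount of 8 (3403 and 3432), at least 100 normalized reads in the higher group (2299 and 2653), and without the 5 libraries with few genes at 0 (2555 and 2832).

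By the limma test few seed coat genes changed at the steps up to heart and more at those after it. The contrast was smaller without 5 libraries with few genes at 0, and with library weights the step from torpedo to early bent had fewer genes than the steps from zygote to quadrant and from quadrant to globular. A total of 177 genes changed from zygote to quadrant (88 up, 89 down), 65 from quadrant to globular (48 up, 17 down) and 30 from globular to heart. With library weights per group these numbers were 1157, 1223 and 326, and by DESeq2 305, 260 and 51; the weights gave 2829 genes for heart to torpedo and 653 for torpedo to early bent. Without these 5 libraries the step from quadrant to globular had 136 genes. From heart to torpedo 5508 genes changed (3607 up, 1901 down), from torpedo to early bent 2213 (1177 up, 1036 down), from early bent to late bent 5753 (2536 up, 3217 down) and from late bent to mature 2606 (1229 up, 1377 down). Of the 3607 genes that rose from heart to torpedo, 487 rose by over 16-fold. With quantile scaling 43.7% of the genes that changed at this step rose and with TMM scaling 51.2%, against 65.5% with the deposited scaling.

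The 30 genes that changed between globular and heart in the seed coat all fell, with a median fold of 40.6. By DESeq2 on the recovered reads 51 genes changed at this step, 5 of them up, by edgeR 9 genes changed, and 847 genes had an unadjusted limma p under 0.05. Of the 30 genes, 23 had identifiers of the 5g series, which holds 13.2% of the tested genes, and 5 had identifiers of the 3g series. Their median was 46.1 and 123.3 normalized reads in the 2 globular seed coat libraries but 0.76 and 1.31 in the 2 globular whole seed libraries. Without the 174 genes that followed this set over the 50 libraries, an alternative chosen after seeing the data, 4 genes changed in the seed coat from globular to heart, 128 from zygote to quadrant, and 305 in the embryo from globular to heart.

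In 5 libraries many genes that were at 0 in the other replicate held a few reads. They were picked against the other replicate alone, so other libraries with few genes at 0 were kept. Seed coat replicate 1 at torpedo, early bent, late bent and mature had 30.3%, 29.9%, 30.3% and 28.6% of genes at 0. Seed coat late bent replicate 2 had 41.1%, the heart seed coats 42.6% and 48.7%, and the ovule libraries 18.2% and 21.6%. Leaving out the 5 thus does not remove the difference in genes at 0 between stages. The 5 were seed coat torpedo replicate 2, seed coat early bent replicate 2, seed coat mature replicate 2, embryo mature replicate 2 and whole seed globular replicate 2. They had 0.465 to 0.642 times as many genes at 0 as the other replicate. Without them 805 seed coat genes changed from heart to torpedo, and from torpedo to early bent 152 rose and 104 fell, an alternative chosen after seeing the data. The seed coat steps from early bent to late bent and from late bent to mature moved by under 1.5 times.

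Single libraries also set the size of the seed coat steps. From zygote to quadrant 86 (45 up, 41 down), 61 (36 and 25), 83 (39 and 44) and 57 (32 and 25) genes changed without zygote replicate 1 or 2 or quadrant replicate 1 or 2. From quadrant to globular 5, 22, 6 and 8 changed without quadrant replicate 1 or 2 or globular replicate 1 or 2, and from globular to heart 8, 2, 1 and 1 without globular replicate 1 or 2 or heart replicate 1 or 2. From heart to torpedo the number was 3065 (1858 up, 1207 down) and 2259 (1461 and 798) without heart replicate 1 or 2, 9113 (5576 and 3537) without torpedo replicate 1 and 664 (525 and 139) without torpedo replicate 2. From torpedo to early bent it was 4712 (2458 up, 2254 down) and 684 (436 and 248) without torpedo replicate 1 or 2 and 924 (419 and 505) without early bent replicate 2, and more genes fell than rose with quantile scaling (1428 and 1656), edgeR (1091 and 1369) and DESeq2 (1264 and 1557) too. From early bent to late bent 3498 genes changed (1624 up, 1874 down) without late bent replicate 2, and more rose than fell with quantile scaling (3205 and 2821) and with at least 100 normalized reads in the higher group (2160 and 1917). From late bent to mature 1367 changed (669 up, 698 down) without late bent replicate 1 and 1688 (712 and 976) without mature replicate 2. At this step more genes rose than fell with no filter (2805 and 1411), with a pseudocount of 8 (1563 and 1535) and without mature replicate 1 (1430 and 1325).

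**Figure D3:**
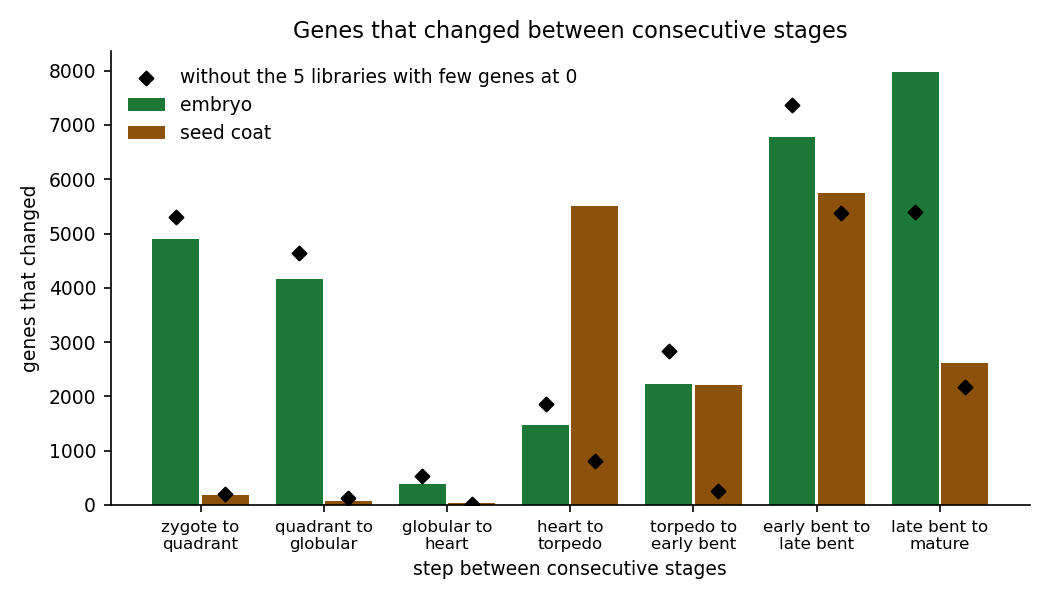
Number of genes that changed between consecutive stages in embryo (green) and seed coat (brown). Diamonds give the number without the 5 libraries with few genes at 0, which drops from 5508 to 805 for the seed coat step from heart to torpedo and from 2213 to 152 up and 104 down for the next step.

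From zygote to mature, 15726 genes changed in the embryo, 8214 up and 7512 down, a balance that turned in 7 of 18 alternatives, among them TMM scaling (7477 up, 8067 down), library weights (6611 and 6631), a filter of at least 50 (5963 and 6837), a pseudocount of 8 (6880 and 7098), at least 100 normalized reads in the higher group (4775 and 5292), and those without mature replicate 2 (6058 and 7141) or the 5 libraries with few genes at 0 (6455 and 7289). Lcu.2RBY.4g079550 had no read in either zygote stage embryo library and stood at 5552 ± 1836 in the mature embryo (SD, n = 2; adjusted p = 1.91e-14), at least 2120-fold higher against a floor of 3 counts per library. Lcu.2RBY.4g049210 rose from 26.6 ± 32.9 to 73659 ± 8095 (SD, n = 2; log2 fold change 12.27, SE 1.19, adjusted p = 3.54e-10), and most of its rise came after late bent, where it stood at 624. Lcu.2RBY.2g075150 was an abundant gene of the zygote stage embryo, at 46105 ± 4911 (SD, n = 2), went down through 5921 at globular to 788 at heart, and had no read in the mature embryo, at least 9181-fold lower (adjusted p = 4.91e-13). Lcu.2RBY.5g047670 followed the same course, from 43745 ± 3726 at the zygote stage over 60439 at quadrant and 1920 at heart to 3.37 ± 4.77 at the mature stage (SD, n = 2; log2 fold change -13.94, SE 1.07, adjusted p = 9.73e-12). In the seed coat the stage means of both genes stayed under 150 normalized reads up to late bent, where the second stood at 135 ± 158 (SD, n = 2). In the mature seed coat the mean of Lcu.2RBY.2g075150 was 1.99. That of Lcu.2RBY.5g047670 was higher there than in the zygote stage seed coat, at 515 against 37.2, opposite to its fall in the embryo.

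In the seed coat 14282 genes changed from zygote to mature, 9005 up and 5277 down. The risers were 5968 without mature replicate 2, which is 1 of the 5 libraries with few genes at 0, and 15023 with no filter. With quantile scaling 49.1% of the changed genes rose, against 63.1% with the deposited scaling. Lcu.2RBY.5g059060 had 1 read in the zygote stage seed coat libraries, reached 46391 at early bent, and stood at 527910 ± 242192 at the mature stage (SD, n = 2; adjusted p = 1.54e-16), where it had the highest mean of all genes in seed coat. The 2 mature seed coat libraries held 356654 and 699165 normalized reads of this gene, which was the most abundant gene only in replicate 2. Its ratio was 1592289, with a 95% counting interval of 285784 to 62892091. Lcu.2RBY.2g049380, also at 1 read in the zygote stage seed coat, stood at 79686 ± 22940 at the mature stage (SD, n = 2; adjusted p = 4.67e-11), and its stage means were uneven, with 11918 at torpedo, 20.0 at early bent and 3409 at late bent. Its ratio was 268814, with a 95% counting interval of 48246 to 10617653. Lcu.2RBY.7g001290, the gene with the highest mean in the zygote stage seed coat at 122812 ± 6665, went down to 9108 at torpedo and 39.01 ± 51.1 at the mature stage (SD, n = 2; log2 fold change -12.81, SE 1.14, adjusted p = 2.13e-10). Lcu.2RBY.6g044130 fell from 38789 ± 2352 to 24.1 ± 32.1 (SD, n = 2; log2 fold change -11.81, SE 0.93, adjusted p = 1.63e-11).

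The zygote to mature changes of embryo and seed coat had many genes in common. Of the 8214 genes that rose in embryo, 4309 also rose in seed coat, where independent lists would share 2513, and of the 7512 that fell in embryo, 3199 also fell in seed coat (1347 for independent lists). Opposite changes were rarer, with 462 genes up in embryo and down in seed coat (1472) and 964 genes down in embryo and up in seed coat (2298). No library entered both comparisons, but they were not independent in all respects. Embryo mature replicate 2 and seed coat mature replicate 2 are both among the 5 libraries with few genes at 0. The deviations of same-numbered embryo and seed coat libraries correlated by 0.467 at the mature stage. The overlap was not computed without these libraries. Across genes, which are not independent replicates, the log2 fold changes of the tissues had a Pearson correlation of 0.479 and a Spearman correlation of 0.506. The change itself differed between the tissues for 10755 genes by the limma interaction test, 4623 with the larger value in embryo and 6132 with the larger value in seed coat. With quantile scaling the share with the larger value in embryo was 53.8%, against 4623 of 10755 genes with the deposited scaling. In the whole seed 10448 genes changed from zygote to mature, 5206 up and 5242 down, a balance that turned in 10 of 18 alternatives.

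Most tested genes varied over the stages. By limma's moderated F-test with a range of at least 2-fold, 22605 genes varied in embryo, 19458 in seed coat and 16944 in whole seed. The mature stage was the stage of the highest mean for 6838 of the embryo genes (30.2%) and 6059 of the seed coat genes (31.1%). In embryo 1845 genes were higher at the mature stage than at each other stage, and 1647 were lower. Embryo mature replicate 2 is 1 of the 5 libraries with few genes at 0. Without these libraries fewer embryo genes were above each other stage at mature. The zygote stage embryo had 730 genes above each other stage, against 99 at quadrant and 1 at globular. In seed coat 15 genes were above each other stage at zygote, 263 at late bent and 603 at mature. Without the 5 libraries with few genes at 0, the seed coat genes above each other stage were 16 instead of 103 at torpedo and 29 instead of 144 at early bent.

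The whole seed changed from a profile close to that of the seed coat to one close to that of the embryo. Between whole seed and seed coat 7 genes differed at the zygote stage, 124 at globular and 702 at early bent, but 9688 at late bent and 12106 at mature. Between whole seed and embryo 5958 genes differed at the zygote stage and 10457 at quadrant, against 2703 at late bent and 3167 at mature. Described as a mixture of the embryo and seed coat profiles of its own stage, the whole seed had an embryo weight of 2.91% ± 4.12 at zygote, 0.35% ± 0.50 at globular and 5.38% ± 0.59 at heart (SD, n = 2). Weights were held between 0% and 100%. Zygote replicate 1 and globular replicate 2 lay at 0% and mature replicate 2 at 100%, so mean and SD are cut off at these stages. The weight was 21.4% ± 5.94 at torpedo, 21.5% ± 8.41 at early bent, 86.6% ± 1.44 at late bent and 94.2% ± 8.13 at mature (SD, n = 2). At torpedo it was 32.6% without seed coat replicate 1 and 11.8% without seed coat replicate 2. Without weighting of genes it was 1.93% at globular and 11.9% at torpedo. Some genes lay outside what a mixture of the tissues can give, differing in the same direction from both: 284 above both at heart, 175 above and 207 below at late bent, and 150 above and 407 below at mature. Without the 5 libraries with few genes at 0 these numbers were 388 at heart, 179 and 249 at late bent, and 57 and 47 at mature. The embryo gene Lcu.2RBY.6g042510 followed this course in the whole seed, from 2.54 ± 0.37 normalized reads at the zygote stage to 8023 ± 291 at late bent (SD, n = 2). The weight describes profiles of messenger RNA and not shares of cells.

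**Figure D4:**
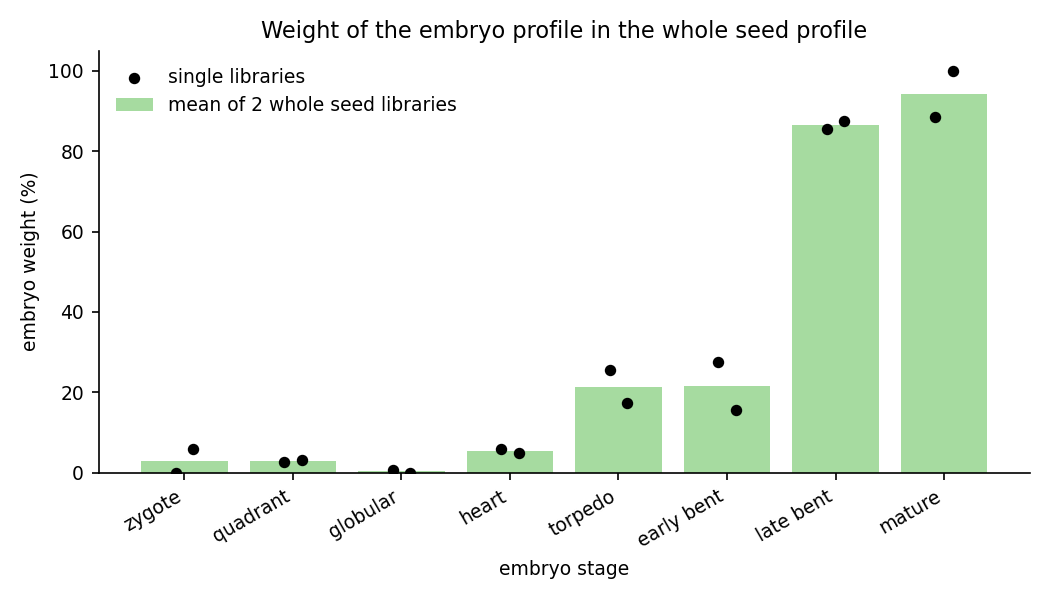
Weight of the embryo profile in the whole seed profile at each of the 8 stages, in percent, as the mean of 2 whole seed libraries (bars) and for each library (points). The mean stays at or under 21.5% up to early bent and reaches 86.6% at late bent.

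The embryo placed its messenger RNA in fewer genes than the seed coat. The effective number of genes, the exponential of the Shannon entropy of the gene shares, was lower in embryo at 8 of 8 stages, with a mean of 2862 ± 1620 in embryo and 5291 ± 1122 in seed coat (SD over 8 stages; exact sign-flip permutation test, two-sided, p = 0.00781, the smallest it can give, adjusted p = 0.0234). In embryo it went down from 5053 ± 52.0 at the zygote stage to 437 ± 36.8 at late bent (SD, n = 2). The 10 most abundant genes held 15.5% ± 11.9 of the embryo libraries and 6.84% ± 3.68 of the seed coat libraries (SD over 8 stages), more in embryo at 7 of 8 stages (exact sign-flip permutation test, p = 0.0156, adjusted p = 0.0234). In embryo that share was 3.68% ± 0.05 at the zygote stage and 37.8% ± 1.33 at late bent, and in seed coat it was 14.3% ± 0.00 at late bent (SD, n = 2). Of the 10 most abundant genes, embryo and seed coat had 2 in common at the zygote stage and 0 at the late bent stage, where embryo and whole seed had 8 in common. Fewer genes reached 10 normalized reads in embryo, 19802 ± 850 against 21134 ± 1582 (SD over 8 stages), in 7 of 8 stages (exact sign-flip permutation test, p = 0.0391, adjusted p = 0.0391). This difference was past the threshold neither without embryo mature replicate 1 (adjusted p = 0.125) nor without seed coat mature replicate 2 (adjusted p = 0.156), which is 1 of the 5 libraries with few genes at 0. Without the 4 of those libraries that are embryo or seed coat, chosen after seeing the data, it was 19547 ± 554 against 20456 ± 762 (SD over 8 stages; adjusted p = 0.0391).

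**Figure D5:**
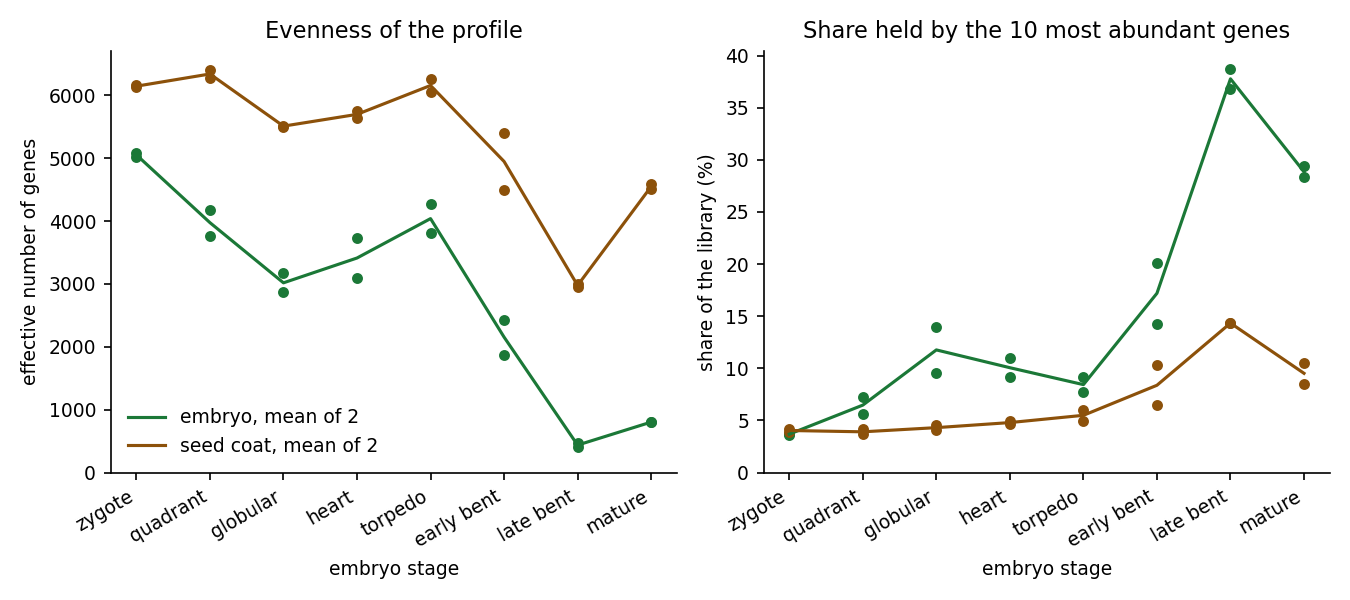
Effective number of genes (left) and share held by the 10 most abundant genes in percent (right) at each stage, with points for the 2 libraries and lines through their means, in embryo (green) and seed coat (brown). The embryo drops to 437 effective genes at late bent, where 10 genes hold 37.8% of the library.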

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

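The tests of sequencing depth and of a common source of reads were planned before their results were seen; the other tests of explanations in this part, the split of tissue labels among them, were chosen after the results were seen.

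The change from zygote to mature differed between embryo and seed coat for 10755 genes by the limma interaction test. The consecutive steps differed between the tissues for 2334 genes from zygote to quadrant, 2525 from quadrant to globular, 21 from globular to heart, 2556 from heart to torpedo, 1722 from torpedo to early bent, 5145 from early bent to late bent and 4890 from late bent to mature. Without the 5 libraries with few genes at 0 the numbers for these steps were 3091, 3313, 62, 1302, 619, 5350 and 3156. Of the 8 genes named for mature versus zygote, 6 changed differently in the 2 tissues; the change in embryo minus that in seed coat follows in log2 units of value + 1. They are Lcu.2RBY.4g079550 (10.29), Lcu.2RBY.4g049210 (6.64), Lcu.2RBY.2g075150 (-12.28), Lcu.2RBY.5g047670 (-17.69), Lcu.2RBY.5g059060 (-16.54) and Lcu.2RBY.2g049380 (-13.38). For genes with 0 or 1 read at one end these values depend on the added 1 and are no bounds.

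The 30 genes that fell in the seed coat between globular and heart were on or off across tissues in a way that stages do not explain, and they differed within a pair of replicates, with a median of 1.07 normalized reads in whole seed early bent replicate 1 and 127.8 in replicate 2. A programme of the seed tissues by stage would place the whole seed between its parts, but at the globular stage the whole seed lay below the lower of embryo and seed coat by a median log2 difference of -4.98 (quartiles -6.20 and -3.87), with the mean of 29 of the 30 genes below both (-5.29 and 29 genes in replicate 1 alone, without the library with few genes at 0); at late bent the whole seed lay above the higher of them by a median of 5.83. A wrong stage label on the late bent whole seed libraries is argued against by their correlation of 0.935 with the late bent embryo, against at most 0.855 with any group of the zygote, quadrant or globular stages. A candidate explanation is a genotype or seed lot difference between the plants used for different libraries, since 76.7% of the genes had identifiers of the 5g series against 13.2% of the tested genes (permutation p = 0.0001 by 10000 random draws, the smallest they can give), which may reflect a few stretches of the genome. The labels give 1 cultivar and no plant or lot, and this hypothesis was found and tested on the same data.

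In 5 libraries far fewer genes were at 0 than in the other replicate of the group. Depth is argued against, since after all libraries were thinned to 13019472 reads the highest of the 5 ratios of genes at 0 was 0.745. Reads from 1 common source, for example genomic DNA, may be involved: across 19635 genes that were quiet in the other libraries, the median Spearman correlation between libraries of different tissues was 0.243, against 0.374 among the 3 seed coat libraries. This explanation cannot be told apart from separate low expression in each tissue, as the value lay between the bounds set beforehand and the seed coat libraries share a tissue. No biological explanation was tested, since both libraries of each pair carry the same tissue and stage.

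The zygote stage embryo held 213 seed coat-high genes at a median of 31.7% of their seed coat level. A fault of 1 library is argued against, since the median shares of the 2 libraries differed by a factor of 1.03. The 90th percentile of the share was 4.10 times the 10th, between the bounds for 1 common share and for separate levels. This test therefore did not decide on seed coat RNA carried over in dissection. Carry-over of all seed coat RNA alike would put every gene at or above 1 common share. The 10th percentile was 15.5%, and 9 of the 213 genes stood under 10%, the lowest at 1.90%. These values argue against such even carry-over as the whole source of the median share. Carry-over from part of the seed coat may account for some of it and cannot be told apart from expression in the young embryo itself. Lcu.2RBY.4g074460 stood at 2.13% of its seed coat level and Lcu.2RBY.7g001290 at 28.6%. The zygote stage as such, which the design names, stays open as an untested biological explanation.

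For embryo versus seed coat over 8 stages, the tissue labels were also exchanged within stages. Among 100 such splits, the real one included, 1 gave as many genes as the real 11441, and the highest of the others gave 3553. A split that mixes the tissues puts their difference into the spread within groups, so fewer genes follow by construction. The splits therefore cannot decide on chance, and they do not bear on dissection or on background reads.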

How the results depend on the processing

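The alternatives without the 5 libraries with few genes at 0, without the genes that follow the set of 30, and with at least 100 normalized reads in the higher group were chosen after seeing the data; the cause of a change was not tested unless stated. All 372 values of the 16 named genes under the alternatives kept their direction and their side of the threshold. These genes were chosen for the largest folds in the same data, so this follows from the choice and does not bear on the other called genes. No total of called genes changed by over 1.5 times with TMM scaling, quantile scaling, a pseudocount of 0.5 or a filter of at least 50. Depth limits the genes with few reads: requiring 100 normalized reads in the higher group leaves fewer genes by construction, 543 for ovule to zygote, 4972, 5210, 6761, 6849 and 7879 for embryo versus seed coat from globular to late bent, 6078 over the 8 stages, 2641, 2547, 170, 767, 1370 and 4952 for the embryo steps other than early bent to late bent, 88, 33, 13 and 3162 for the first 4 seed coat steps, 10067 and 8541 for mature versus zygote in embryo and seed coat, and 12513 seed coat genes varying over stages.

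The labels do not say whether equal replicate numbers pair the samples. The deviations of embryo and seed coat libraries with the same number correlated by -0.109 to 0.467, above 0.1 at 3 of 8 stages, which does not decide it. A block on the replicate number moved ovule to zygote from 1150 to 1204 genes and the 30 seed coat genes to 42, and changed no count by over 1.5 times.

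Library weights per group gave 4794 genes for ovule to zygote, 8062 for embryo versus seed coat at torpedo, 659 and 4099 for the embryo steps globular to heart and late bent to mature, and 1157, 1223, 326, 2829 and 653 for the first 5 seed coat steps. Without the 5 libraries the counts were 2619 for ovule to zygote and 136, 805 and 2.6e+02 (152 up, 104 down) for the seed coat steps quadrant to globular, heart to torpedo and torpedo to early bent. With a pseudocount of 8, 7455 genes differed over the 8 stages and 281, 154 and 16 changed at the first 3 seed coat steps; with no fold required 21848 differed over the 8 stages. With no filter the seed coat steps quadrant to globular, globular to heart and late bent to mature had 42, 18 and 4216 genes, the last with 2805 up and 1411 down. The spread of the compared tissues alone gave 163, 842 and 1454 genes for the embryo steps from globular to early bent and 50 for seed coat globular to heart. DESeq2 gave 305, 260 and 51 genes for the first 3 seed coat steps and edgeR 9 for the third of them, which had 4 without the genes that follow the set.

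The embryo weight of the whole seed without weighting of genes was 2.12% at quadrant, 1.93% at globular, 3.63% at heart, 11.9% at torpedo and 94.3% at late bent; on the log2 scale it was 0.20%, 1.68%, 2.63%, 14.5% and 83.5% at these stages. With genes of at least 1000 normalized reads it was 6.12% at heart.

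Leaving out 1 library, which assumes that the lone sample varies like the other groups, gave 409 to 590 genes for ovule to zygote and 7654 to 13396 for embryo versus seed coat at torpedo. For the embryo steps from globular on it gave 156 to 259, 903 to 979, 1049 to 1884, 4208 to 7109 and 4438 to 10441 genes, and for the 7 seed coat steps 57 to 86, 5 to 22, 1 to 8, 664 to 9113, 684 to 4712, 3498 to 5757 and 1367 to 2755. The embryo weight was 4.20% to 6.74% at heart, 11.8% to 32.6% at torpedo and 83.4% to 89.6% at late bent. The difference in genes with at least 10 normalized reads, embryo minus seed coat, was -1643 to -1023.

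The counts by direction depended more on the processing than the totals. With quantile scaling the balance of higher and lower genes turned for 16 comparisons and with TMM scaling for 6. With quantile scaling the risers from ovule to zygote went from 483 to 910, the embryo genes that fell from zygote to quadrant from 3833 to 2151, and the seed coat-high genes from 8126 to 4602 at torpedo, from 8153 to 4828 at early bent and from 7716 to 4788 over the 8 stages. With TMM scaling the seed coat genes that fell from heart to torpedo went from 1901 to 2884. With a filter of at least 50 the risers from zygote to mature in seed coat went from 9005 to 5900, and the balance turned for mature versus zygote in embryo (5963 up, 6837 down). Among called genes with at least 100 normalized reads in the higher group it turned for 7 comparisons, ovule to zygote among them. The lower number of genes with at least 10 normalized reads in embryo was not past the threshold without embryo mature replicate 1 or without seed coat mature replicate 2 (adjusted p = 0.125 and 0.156); over all its alternatives the adjusted p lay between 0.0117 and 0.156.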
